A study of Mus musculus with 6 samples.

How the data were processed

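RNA-seq libraries labelled as olfactory bulb of aged mice were compared between 3 homozygous Mitf mutants (mi-vga9 allele) and 3 C57BL/6J wild-type samples, grouped by genotype as the labels give it. RNA was extracted with the Monarch Total RNA Miniprep kit and made into libraries with the TruSeq RNA v2 kit, per the labels' protocols. The sequencer output was converted with bcl2fastq 2.20 and transcripts were quantified with kallisto, per the submitters' processing notes, which name the GRCm39 mouse assembly. The kallisto version and the transcript annotation are not given in the sources used here.

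The authors deposited 2 kallisto tables per sample, each with an estimated count and a TPM value (abundance scaled by transcript length and library) for the same 137436 transcripts. Estimated counts are fractional because kallisto shares reads between similar transcripts, so members of near-identical gene families are uncertain. The columns of the deposited tables, effective transcript length among them, carry kallisto's own names, per the file headers. The estimates of the 2 tables differed in 0 transcripts by more than 1e-05 of the value and 0.001 counts. The rule for choosing a table ended in a tie, and the table written at full precision was used.

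Transcript identifiers without versions were matched to GENCODE M21 on GRCm38, the annotation at hand. Of the transcripts, 135051 (98.3%) matched, 2385 did not, and 49130 genes had at least 1 matched transcript. Gene names, positions and distances therefore come from GRCm38. Unmatched transcripts held 4.35% to 12.9% of the counts of a library and were left out of library sizes and tests. Nearly all of that was a single transcript, ENSMUST00000240377.

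Estimated counts were summed per gene and rounded to whole numbers. Genes were filtered with filterByExpr, scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test, robust estimates) under R 4.3.3, with genotype as the single term. Benjamini-Hochberg adjusted p below 0.05 over the 22739 tested genes counted as a call. Standard errors were the log2 fold change divided by the root of F. Levels are CPM after TMM scaling over the tested genes, with a prior count of 2 on the log2 scale. Levels of sex-linked genes and of genes looked up later are CPM with TMM factors over all genes, which differ slightly.

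Gene lists were fixed before the data were examined: 38 lists of cell type markers, pathways and checks with 629 entries, of which 4 did not match a single gene. A gene listed under 2 names counted once. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. A set of 8 further lists of markers of other brain regions, pituitary and eye was written after the data were first examined and adjusted separately; the pituitary list had fewer than 3 tested members and was not tested. Genes near Mitf were compared with all other tested genes by a two-sided Fisher's exact test within 10 Mb.

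The genes named in the text followed a rule fixed before the data were examined. It took Mitf, Tfe3, Tfeb, Tfec, Kcnd3, Avp, Th, Gfap and Aif1 in any case. It took up to 15 genes per direction with the greatest change among called genes whose groups did not overlap and whose mean log2 CPM was at least 0, leaving out predicted genes and pseudogenes. It also took called list members and up to 4 members of each changed list by smallest p, and the 5 smallest p in a direction with fewer than 5 calls. Genes outside the rule were chosen after their values were seen, except Xist, the Y-linked genes and the tectum markers. Some genes the rule takes are not reported here.

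Alternatives chosen before the data were examined were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a mean of at least 1 CPM, labelled sex as covariate, the replicate number as block, each library left out, the other deposited table, a transcript length offset, and robust estimation off. Deposited TPM values were tested with limma as log2(TPM + 1) with a mean TPM of at least 0.5, as log2(TPM + 0.1), and without the filter. Mutant 1 alone against wild type, and TPM rescaled without Mir6236, were added after the data were examined.

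The pipeline was tested on simulated counts with 200 changed genes. With the spread of the 3 mutant and 3 wild-type libraries, it recovered 4.62% of genes changed 2-fold, 50.8% of those changed 4-fold and 72.1% of those changed 8-fold, over 22256 genes, with 6 of 84 calls false (7.14%). For mutant 1 alone against wild type, over 24058 genes, it recovered 37.3%, 58.7% and 87.1% at these folds, with 35 of 151 calls false (23.2%). In both simulations camera called the planted list and 0 of 30 unchanged lists. Correlation between list members was not examined in these simulations, so that count does not cover lists whose members vary together. Between the 3 mutant and 3 wild-type libraries, the estimated correlation ran from -0.152 for the Mitf family to 0.853 for oligodendrocytes.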

Results

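RNA labelled as from olfactory bulb was measured in 6 libraries from aged mice, 3 homozygous for the mi-vga9 allele of Mitf and 3 from C57BL/6J wild type. Mitf encodes a basic helix-loop-helix leucine zipper transcription factor best known from pigment cells, and mi-vga9 arose by insertion of a transgene at the locus. The study compared the genotypes to ask which genes differ in the bulb without Mitf. Markers of bulb neurons, below, were low in the 3 wild types and mutant 1, so differences are given between the libraries as labelled. The labels give ages of 25, 25 and 26 months for wild types 1 to 3 and of 25, 25 and 22 months for mutants 1 to 3. Wild type 3 and mutant 1 are labelled male, the other 4 female. The deposited estimated counts summed to 111148767, 118995143 and 86955423 in wild types 1 to 3, and to 127503446, 152318648 and 106165515 in mutants 1 to 3. At these depths 3 counts equalled 0.0233 to 0.0354 CPM, which covers counting error only. The labels do not state that every library came from a different mouse, so p-values measure the spread between libraries.

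Mitf itself was lower in every mutant library than in every wild-type library. It lay at 16.3 ± 1.03 CPM in wild type and at 1.66 ± 0.492 CPM in the mutants (SD, n = 3 each), a log2 fold change of -3.29 (SE 0.25, edgeR adjusted p = 0.017). The mutant libraries held 1.20, 2.18 and 1.61 CPM, so by this gene each library matched its genotype label. Mitf spans chromosome 6 from 97807052 to 98021349 on GRCm38. Its most abundant transcript, Mitf-202, lay at 1470 ± 249 estimated counts in wild type and 96.6 ± 45.7 in the mutants (SD, n = 3 each), while the retained-intron transcript Mitf-206 lay at 17.7 ± 9.33 and 21.1 ± 13.6, in the same order. Transcripts Mitf-207 and Mitf-208 held 149 ± 45.0 and 33.9 ± 15.2 estimated counts in wild type, against 65.9 ± 39.2 and 0 in the mutants. Transcripts were not tested. The Mitf call was lost without wild type 1, 2 or 3 (edgeR adjusted p = 0.159, 0.159 and 0.206) and without mutant 2 or 3 (adjusted p = 0.0548 and 0.101). Over all 6 such fits the log2 fold change ranged from -3.54 to -3.10.

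The related factors Tfe3 and Tfeb, which share targets with Mitf at lysosomal genes, did not pass. Tfe3 lay at 34.8 ± 0.737 and 37.3 ± 3.81 CPM and Tfeb at 15.9 ± 1.17 and 10.4 ± 4.03 CPM in wild type and mutants (SD, n = 3 each; edgeR adjusted p = 0.555 and 0.224). Tfec reached at most 0.116 CPM in any library and was not tested. As a list, the Mitf family fell (median log2 fold change -0.62, camera adjusted p = 0.0281), but of its 3 tested members only Mitf passed. The adjusted p was 0.643 with an estimated correlation. Kcnd3, a subunit of A-type potassium channels, lay at 130 ± 7.36 CPM in wild type and 182 ± 54.0 in the mutants and did not pass (adjusted p = 0.243). Its level was 120 CPM in mutant 1, below all 3 wild types, and 211 and 215 CPM in mutants 2 and 3.

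Xist, which is transcribed from the inactive X chromosome, and Y-linked genes did not match the labelled sex of mutant 1. This library, labelled male, held 493 CPM of Xist and 1.58 CPM summed over Ddx3y, Eif2s3y, Kdm5d and Uty. Wild type 3, the other library labelled male, held 0.220 and 123 CPM. The 4 libraries labelled female held 786 to 1743 CPM of Xist and 1.42 to 3.73 CPM of the Y genes. Mutant 1 is named by its label throughout.

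**Figure D1:**
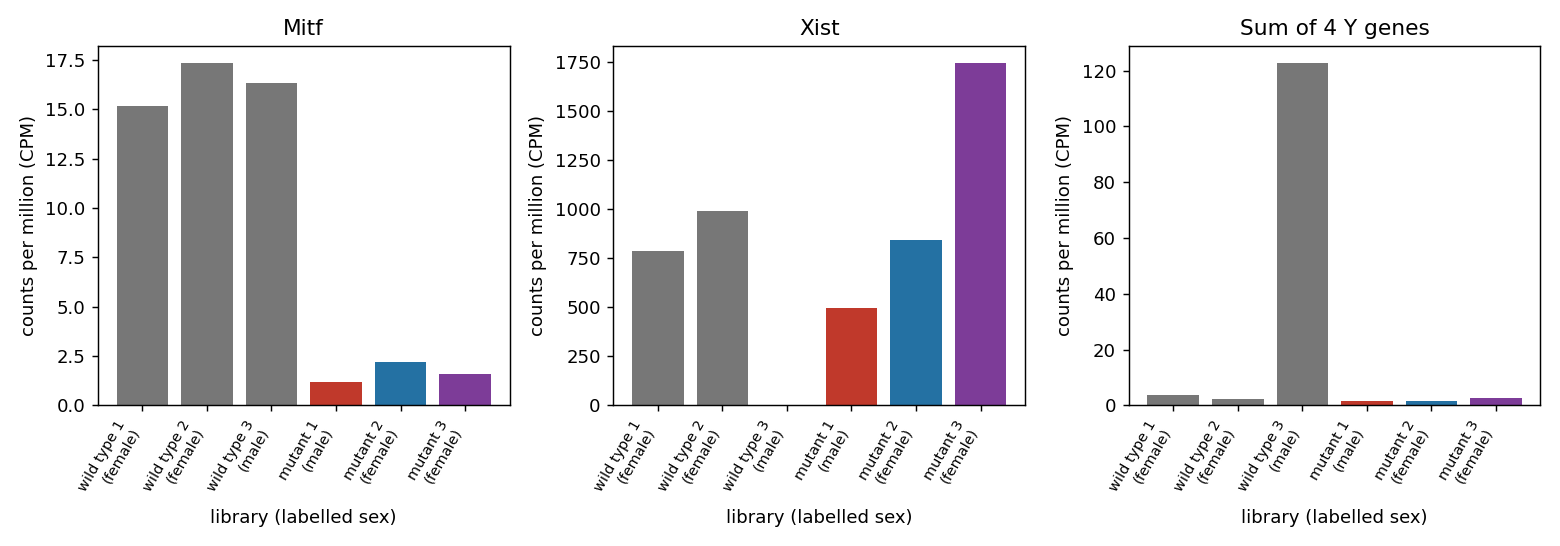
Bars give the CPM (linear axes from 0) of Mitf, of Xist and of 4 summed Y-linked genes in each of the 6 libraries, with the labelled sex below. Mitf lies lower in each of the 3 mutant libraries than in any wild type, and mutant 1, labelled male, has 493 CPM of Xist and 1.58 CPM of the Y genes.

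Libraries of mutants 2 and 3 stood apart from the other 4 in markers of olfactory bulb neurons. Cdhr1, a cadherin of mitral and tufted cells, lay at 651 and 563 CPM in mutants 2 and 3, at 2.63 CPM in mutant 1 and at 0.425 ± 0.198 CPM in wild type (SD, n = 3). Dlx1, a homeobox gene of bulb interneurons, lay at 294 and 261 CPM in mutants 2 and 3, at 0.242 CPM in mutant 1 and at 0.237 ± 0.153 CPM in wild type. Th, the rate-limiting enzyme of dopamine synthesis in periglomerular cells, lay at 160 and 156 CPM against 5.73 CPM in mutant 1 and 13.1 ± 4.19 CPM in wild type. With mutant 1 on the side of wild type, Cdhr1, Dlx1 and Th did not pass between the groups (edgeR adjusted p = 0.156, 0.156 and 0.185).

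The converse held for genes known from the cerebellum, which were looked up after the data were examined and lie outside the naming rule. Gabra6, a GABA receptor subunit of cerebellar granule neurons, lay at 358 to 401 CPM in wild type and 370 CPM in mutant 1, but at 0.0311 and 0.0118 CPM in mutants 2 and 3. Cbln3 lay at 1631 to 1782 CPM in wild type, 1663 CPM in mutant 1, and 2.52 and 1.70 CPM in mutants 2 and 3. None of the 16 cerebellum markers in the later list passed between genotypes (0 higher, 0 lower, also adjusted over the list alone). The list fell as a whole (median log2 fold change -1.58, camera adjusted p = 2.66e-05). Its adjusted p was 0.757 with an estimated correlation. Across genes, log2 CPM correlated at r = 0.989 to 0.990 between wild types, 0.978 to 0.984 between mutant 1 and wild type, 0.982 between mutants 2 and 3, and 0.923 to 0.930 between those 2 and wild type. Mutant 1 correlated at 0.948 with mutant 2 and 0.939 with mutant 3. Genes are not independent replicates in these correlations.

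**Figure D2:**
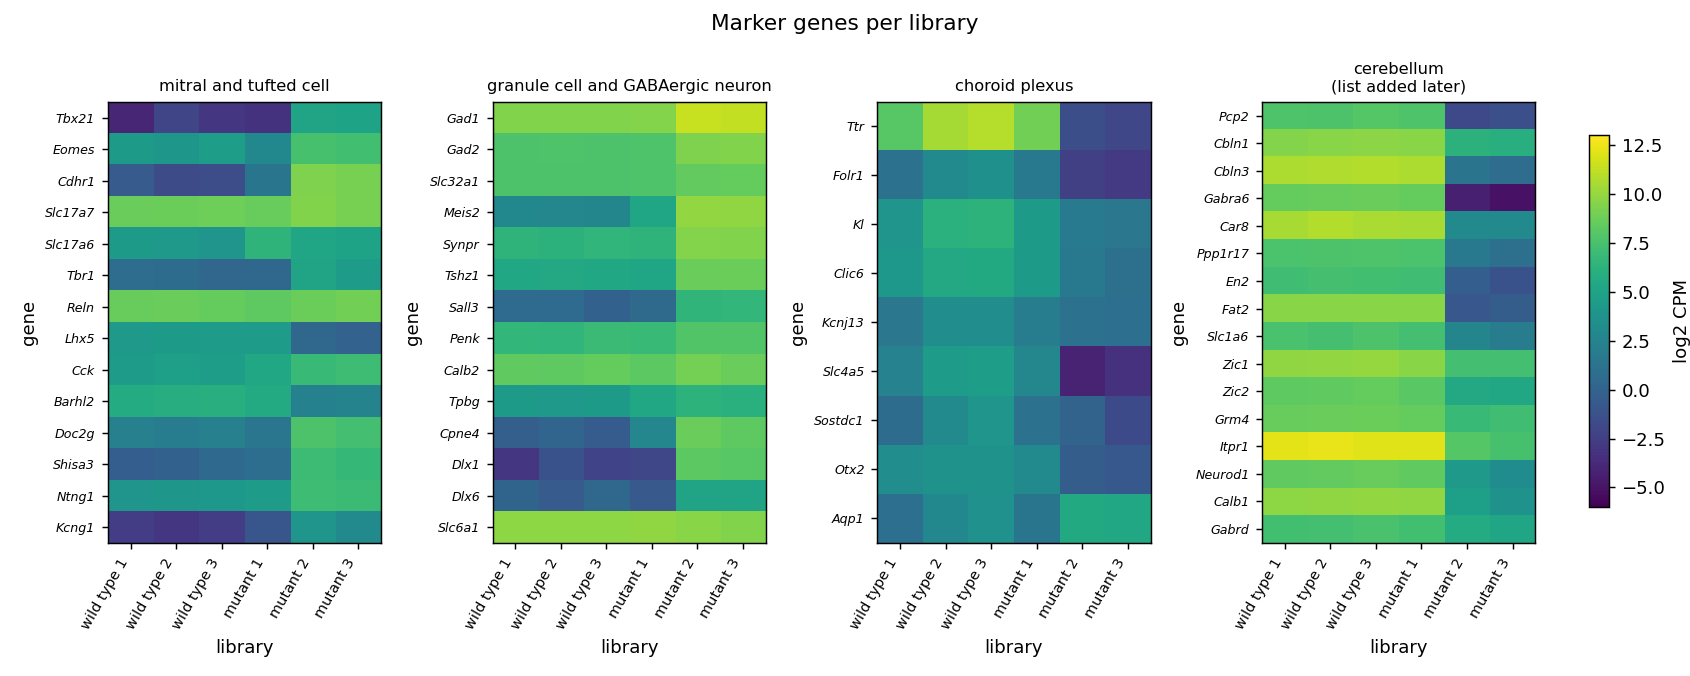
Colour gives log2 CPM of single genes (rows) in the 6 libraries (columns) for 3 lists fixed in advance and for the cerebellum list added later. Mutant 1 lies near the wild types in most of these genes, as in Gabra6 at 370 CPM and Dlx1 at 0.242 CPM. Mutants 2 and 3 have 294 and 261 CPM of Dlx1.

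Between genotypes, 26 genes were higher and 9 lower in the mutants among 22739 tested (edgeR). The 3 mutant libraries lay on one side of the 3 wild types in all 35 called genes, and in 32.2% of all tested genes, against 10% by chance if all 6 libraries were exchangeable. With mutants 2 and 3 standing apart together, that share does not measure an effect of genotype. Fold changes of the called genes likewise do not separate genotype from tissue markers. Mutants 2 and 3 were high in bulb markers and the wild types in cerebellum markers. Mutant 1 lay nearer the wild types in these, but markers of the tectum were higher in it, as given below. Cbln2, a secreted synapse organizer, rose 48.7-fold from 0.698 ± 0.170 to 34.0 ± 12.98 CPM (SD, n = 3 each; log2 fold change 5.61, SE 0.41, adjusted p = 0.017). Nrgn, a calmodulin-binding postsynaptic protein, rose 21.4-fold from 6.60 ± 1.83 to 142 ± 11.1 CPM (log2 fold change 4.42, SE 0.25, adjusted p = 0.00596). The serotonin receptor gene Htr1a rose 28.04-fold, the calcium sensor gene Doc2a 25.7-fold, and the neurokinin receptor gene Tacr3 21.3-fold (adjusted p = 0.0384, 0.0377 and 0.017). Glra2, a glycine receptor subunit, rose 5.78-fold with little spread, from 1.11 ± 0.0705 to 6.42 ± 0.222 CPM. Asic4, Hs3st4, Cdh9, Gpr26, Pde11a, Atg9b, Tox2 and Vstm2b rose by log2 fold changes of 4.12, 3.47, 3.43, 3.09, 2.77, 2.44, 2.32 and 2.13, and Slit1 rose 8.02-fold.

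Besides Mitf, the lower genes named by the rule were Pttg1, Agfg2 and Wdfy1. Pttg1 encodes securin, an inhibitor of sister chromatid separation, and fell from 17.0 ± 1.53 to 0.548 ± 0.295 CPM (log2 fold change -4.95, SE 0.41, adjusted p = 0.0189). Wdfy1 fell from 64.2 ± 2.14 to 19.7 ± 1.20 CPM (log2 fold change -1.71, SE 0.10, adjusted p = 0.00596), and Agfg2 from 45.5 ± 4.87 to 12.9 ± 2.95 CPM (log2 fold change -1.82, SE 0.19, adjusted p = 0.0388). The other 5 lower genes lay outside the rule and are named here after their values were seen. They were Tex13b and 4 predicted genes of a repeated family on chromosome 4, Gm17167, Gm13301, Gm5859 and Gm17081, which start between 42206998 and 42239725 on GRCm38. Because reads of near-identical copies are shared, these 4 are uncertain.

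Mutant 1 alone against the 3 wild types, a fit added after the data were examined, gave 480 higher and 160 lower genes, among them 34 of the 35, all in the same direction. The 35 calls also used these 4 libraries, so this overlap is no independent check. In that fit the lone library is assumed to vary like the wild types, and in its simulation 35 of 151 calls were false. Nrgn was the exception, with a log2 fold change of 4.37 and an adjusted p of 0.0633. Without mutant 1, 4977 genes were higher and 3987 lower, including all 35. Without wild type 1, 2 or 3 and without mutant 2 or 3, edgeR called 0, 0, 2, 0 and 0 genes higher and 2, 2, 2, 1 and 2 lower. At unadjusted p below 0.05 these fits held 2679, 3308, 3060, 3104 and 4646 genes in either direction, against 5452 in the full comparison. DESeq2 called 1959 higher and 720 lower. On deposited TPM values limma called 347 higher and 1270 lower, with the median of all genes at -0.47 on the log2 scale. The higher genes were 21.5% of these calls, against 74.3% by edgeR on counts. Mir6236 held 11.6% to 62.2% of a library's TPM, and on TPM rescaled without it, a fit also added after the data were examined, 51.9% of the calls were higher.

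**Figure D3:**
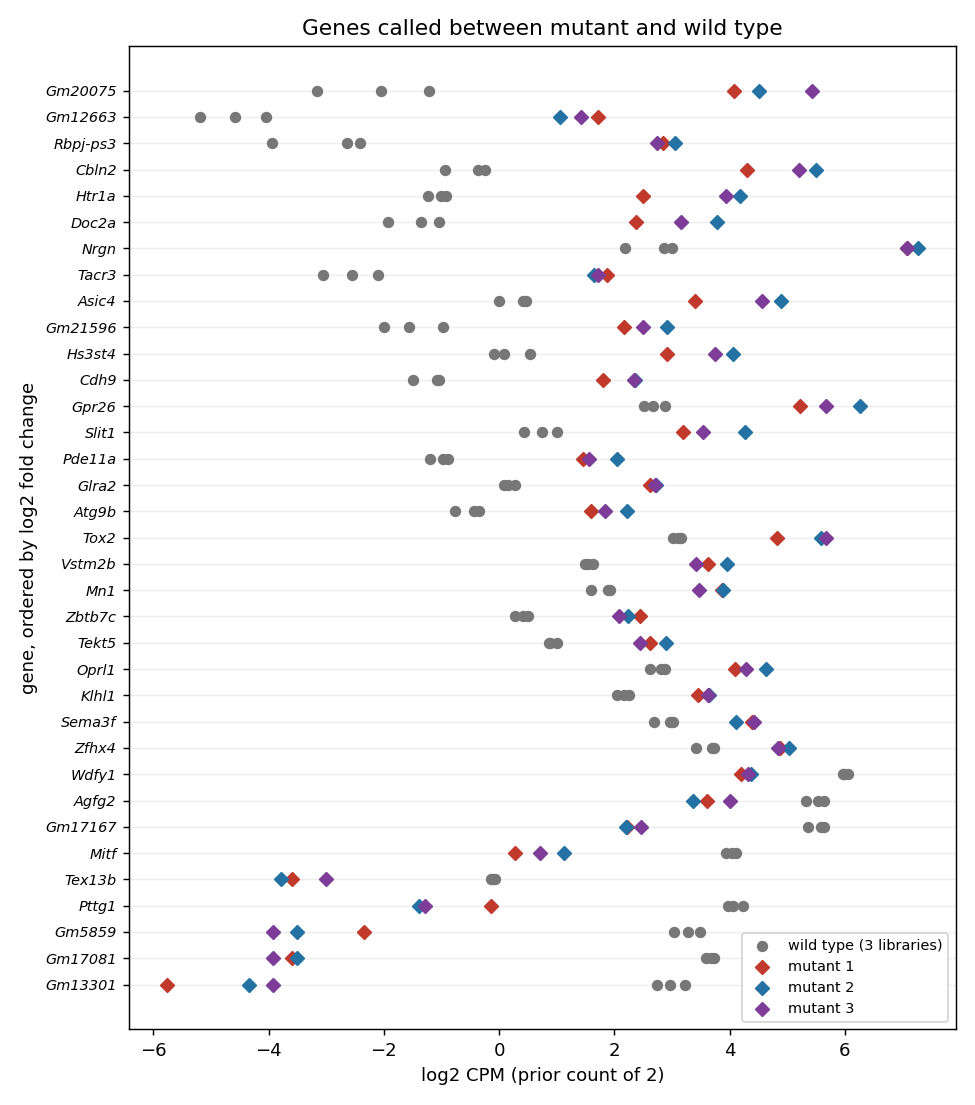
Points give log2 CPM of the 35 called genes (rows, ordered by log2 fold change) in each library, circles for the 3 wild types and diamonds for mutants 1 to 3. In each row the mutants lie on one side of the wild types, with Cbln2 at 19.8, 45.2 and 37.0 CPM in mutants 1 to 3.

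Of the 38 lists, 16 changed by camera at the preset correlation. No list change given here separates genotype from the bulb and cerebellum markers that part mutants 2 and 3 from the wild types. That holds for glial and metabolic lists too. With an estimated correlation 0 did, with 1 list at an unadjusted p below 0.05, and fry called 2, the Mitf family and striatum (adjusted p = 0.00399 and 0.0224). Lists of granule and of mitral and tufted cells rose, while those of periglomerular cells and neuroblasts did not pass. The periglomerular list had 7 of 9 members tested. The filter left out Slc6a3 and Trh, named here after their values were seen. Slc6a3 lay at 21.3 and 11.98 CPM and Trh at 122 and 85.2 CPM in mutants 2 and 3. In mutant 1 and the wild types they reached at most 0.0731 and 0.0487 CPM. Calb1, a tested member, lay at 851 to 963 CPM in wild type and 26.6 and 13.2 CPM in mutants 2 and 3. The granule cell and GABAergic neuron list had a median log2 fold change of 2.10 (camera adjusted p = 1.18e-05, adjusted p = 0.643 with an estimated correlation). Of its 14 tested members 0 passed over all genes, and 12 were higher adjusted over the list alone. Meis2 and Cpne4 lay at 636 ± 519 and 243 ± 211 CPM in the mutants against 7.02 ± 0.337 and 0.894 ± 0.216 CPM in wild type (SD, n = 3 each). The mitral and tufted cell list rose likewise (median 2.46, adjusted p = 0.00194, and 0.643 with an estimated correlation). Of its 14 members 0 passed over all genes and 9 were higher adjusted over the list alone, with Cdhr1 and Kcng1 of smallest p. The median member of the granule cell list lay 0.10, 2.54 and 2.45 above the wild-type mean log2 CPM in mutants 1, 2 and 3. For the mitral and tufted list the medians were -0.04, 3.06 and 2.88. In mutant 1 alone against wild type both lists were higher by camera (adjusted p = 3.32e-06 and 0.00463, and 0.317 and 0.493 with an estimated correlation). There 3 of 14 granule list members passed as higher, among them Meis2 (5.32-fold) and Cpne4 (7.97-fold). Of the 14 mitral and tufted members 7 had higher and 7 lower values. Of these, 3 passed as higher, among them Cdhr1 (6.23-fold) and Slc17a6 (4.70-fold), and Eomes as lower, while adjusted over the list alone 5 were higher and 3 lower. Slc17a6 and Eomes lie outside the rule and are named after their values were seen, and Slc17a6 also stands on the thalamus list added later. Markers of other regions were higher in this library too, with 6 of 8 tectum markers above every other library by over 1 on the log2 scale.

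Forebrain lists rose too. The striatum list (median log2 fold change 1.67, camera adjusted p = 0.00277, and 0.643 with an estimated correlation) had 0 of 11 members passing over all genes, 8 higher adjusted over the list alone, and medians of 0.59, 1.83 and 1.46 in mutants 1 to 3. Tac1, which encodes substance P, lay at 3.77 ± 1.34 CPM in the mutants against 0.346 ± 0.106 in wild type, and Rasd2 at 60.5 ± 15.4 against 26.3 ± 1.15 CPM. The list of cortex and anterior olfactory nucleus (median 2.42, adjusted p = 0.0046, and 0.643 with an estimated correlation) had 1 of 13 members, Nrgn, higher over all genes, 7 higher adjusted over the list alone, and medians of 0.06, 3.26 and 2.22. Its transcription factor Bcl11b lay at 9.96, 216 and 211 CPM in mutants 1 to 3 and 2.36 ± 0.414 CPM in wild type. Immediate early genes rose (median 1.14, adjusted p = 0.0046, and 0.664 with an estimated correlation), with 0 of 20 passing over all genes. Adjusted over the list alone, 2 were higher and 1 lower. Jun lay at 51.5 ± 3.78 and 105 ± 20.8 CPM and Egr3 at 0.853 ± 0.645 and 36.3 ± 28.5 CPM in wild type and mutants. The median immediate early gene lay at -0.09, 2.25 and 0.72 against wild type in mutants 1 to 3.

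Among glial and barrier lists, olfactory ensheathing glia rose (median log2 fold change 2.73, camera adjusted p = 0.00658, and 0.643 with an estimated correlation), with 0 of 11 members passing and 8 higher adjusted over the list alone. Its median member lay at 0.13, 3.20 and 2.75 against wild type in mutants 1 to 3. Gldn and Frzb lay at 1.95 ± 1.81 and 54.5 ± 46.1 CPM in the mutants against 0.191 ± 0.0157 and 2.73 ± 0.1004 CPM in wild type. Homeostatic microglia rose (median 0.56, adjusted p = 0.0046, and 0.662 with an estimated correlation) with 0 of 16 members passing, also over the list alone. Its medians were 0.18, 0.83 and 0.59 in mutants 1 to 3, and it did not pass in mutant 1 alone (adjusted p = 0.157). Sall1 and Aif1 had the smallest p. Aif1 lay at 1.56 ± 0.121 and 2.67 ± 0.367 CPM (edgeR adjusted p = 0.156). Sall1, known from microglia in brain, lay at 17.0, 253 and 269 CPM in mutants 1 to 3 and 13.2 ± 1.64 CPM in wild type. Its rise in mutants 2 and 3 was far above the list medians there, so it is not assigned to microglia. Oligodendrocyte precursors rose (median 0.50, adjusted p = 0.0164, and 0.643 with an estimated correlation) with 0 of 9 passing and 5 higher over the list alone, among them Olig1 and Olig2, at medians of 0.17, 0.46 and 0.57 in mutants 1 to 3. Choroid plexus genes fell (median -2.65, adjusted p = 0.00476, and 0.658 with an estimated correlation) with 0 of 9 passing and medians of -0.91, -3.63 and -4.25 in mutants 1 to 3, low in the 2 libraries that were also low in cerebellum markers. Sostdc1 and Kl lay at 8.13 ± 6.63 and 55.8 ± 35.3 CPM in wild type and 1.16 ± 0.952 and 8.87 ± 9.80 CPM in the mutants. Ependymal genes fell (median -0.66, adjusted p = 0.00905, and 0.658 with an estimated correlation), all 10 with lower values and 0 passing, with medians of -0.11, -1.03 and -1.11 in mutants 1 to 3. Examples are Hydin and Cfap126 at log2 fold changes of -0.88 and -0.76. Gfap, the astrocyte filament, lay at 381 ± 80.9 and 379 ± 109 CPM (adjusted p = 0.988).

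Metabolic lists changed by smaller amounts, in the same comparison of libraries that differ in bulb and cerebellum markers. Cholesterol synthesis rose (median log2 fold change 0.47, camera adjusted p = 0.000187, and 0.643 with an estimated correlation), with 0 of 22 members passing over all genes and 10 higher adjusted over the list alone. Msmo1 lay at 23.5 ± 1.51 and 34.9 ± 4.39 CPM in wild type and mutants (SD, n = 3 each). The median member lay 0.32, 0.70 and 0.30 above wild type in mutants 1 to 3. Nuclear oxidative phosphorylation genes rose (median 0.19, adjusted p = 0.0061, and 0.658 with an estimated correlation) with 0 of 36 passing. Ndufv2 and Atp5c1 were at log2 fold changes of 0.51 and 0.34. Mitochondrially encoded genes rose (median 0.46, adjusted p = 0.00732, and 0.664 with an estimated correlation) with 0 of 13 passing, at medians of 0.14, 0.30 and 0.82 in mutants 1 to 3. Mutant 3 also stood apart with 62.2% of its TPM on Mir6236, 2.77% of its counts on Lars2 and 0.824% on mitochondrial ribosomal RNA. The mitochondrial gene mt-Co1 lay at 15830 ± 2728 and 23640 ± 2789 CPM, and mt-Cytb had a log2 fold change of 0.74. The type I interferon list rose (median 0.42, adjusted p = 0.0145, and 0.719 with an estimated correlation) with 0 of 21 passing and 1, Ifit2, higher over the list alone. Ifit2 lay at 10.8 ± 1.11 and 25.8 ± 7.88 CPM and Ifi44 at 1.98 ± 0.316 and 3.60 ± 0.399 CPM in wild type and mutants. The median interferon gene lay at 0.77, 0.62 and -0.30 against wild type in mutants 1 to 3.

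The other 22 lists did not pass camera. Adjusted p was 0.0695 for A-type and 0.228 for other potassium channels, 0.0754 for olfactory sensory neurons, 0.0799 for neuroblasts, 0.0619 for synapse genes and 0.533 for dopaminergic periglomerular cells. It was 0.177 for astrocytes, 0.369 for reactive astrocytes, 0.263 for disease-associated microglia, 0.309 for oligodendrocytes, 0.969 for endothelial cells and 0.311 for meningeal fibroblasts. Pigment cell genes (0.228), red blood cells (0.609), lymphocytes (0.826) and sex-linked genes (0.309) did not pass either. The same held for lysosome and autophagy genes (0.328), antigen presentation (0.552), p53 response (0.733), neurodegeneration-linked genes (0.969), heat shock (0.744) and the circadian clock (0.692). For endothelial cells the median and mean log2 fold change were -0.06 and -0.02 while camera pointed up. Of lysosomal genes, Atg9b alone passed over all genes (5.44-fold higher, edgeR adjusted p = 0.043). Adjusted over the list alone, 3 A-type and 4 other potassium channel genes, 4 neuroblast genes, 4 meningeal genes and 1 gene each for periglomerular cells, the p53 response and lysosomes were higher. On the same count, 4 sex-linked genes, 1 meningeal gene and the pigment cell gene Oca2 were lower. Oca2 lies outside the rule and is named after its values were seen. The 4 sex-linked genes are Y-linked, and their fall rests mainly on wild type 3. Their sum was 123 CPM in that library and 1.42 to 3.73 CPM in the others, wild types 1 and 2 among them.

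The list of the transgene's vasopressin promoter and Mitf's neighbours rose (median log2 fold change 0.30, camera adjusted p = 0.00905, and 0.643 with an estimated correlation), with 0 of 11 members passing and 3 higher over the list alone. Avp, the vasopressin gene, lay at 0.0781 ± 0.0491 and 0.761 ± 0.353 CPM in wild type and mutants (SD, n = 3 each), and Fam19a4 at 0.0222 ± 0.00385 and 0.211 ± 0.120 CPM. Within 10 Mb of Mitf, 1 of 109 tested genes was called, Mitf itself, against 34 of 22630 elsewhere (Fisher's exact test, two-sided, p = 0.155).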

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

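A single unmatched transcript, ENSMUST00000240377, which enters no comparison, held more of the counts in the libraries of mutants 2 and 3 than in the control libraries. It took 8.14% and 12.4% of the counts of mutants 2 and 3, against 4.61%, 3.82% and 4.78% in wild types 1 to 3 and 4.49% in mutant 1. Its gene was not in the annotation used here, and no explanation was tested.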

How the results depend on the processing

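Mutant 1 alone against wild type and TPM rescaled without Mir6236 were chosen after the data were examined; the other alternatives were planned. Against 26 genes higher and 9 lower, DESeq2 gave 1959 and 720, no filter 64 and 17, and mutant 1 alone 480 and 160. Labelled sex as covariate gave 53 higher and 9 lower. That term codes mutant 1 as male, against its Xist and Y-linked RNA, so it does not adjust for sex as expressed. log2(TPM + 1) gave 347 and 1270, log2(TPM + 0.1) 301 and 1137, unfiltered log2(TPM + 1) 3 and 5, and the rescaled TPM 14 higher and 13 lower. Higher calls ranged from 0 to 4977 and lower calls from 1 to 3987 over the fits without a library, the largest without mutant 1. Upper-quartile factors moved the median of all genes to -0.11, TPM to -0.47, -0.58 and -0.16, and rescaled TPM to -0.18. The cause of these shifts was not tested.

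The replicate numbers do not pair the libraries: same-numbered deviations from the group means correlated at -0.075, 0.15 and -0.005 across genes, and wild types 1 and 3 and mutants 1 and 3 correlated better with a library of another number. With the replicate block, 1 gene was higher and 1 lower, and Mitf's log2 fold change was -3.33 (adjusted p = 0.143).

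Mitf kept its direction under every alternative. It passed under all but the replicate block, 5 of the 6 fits without a library (adjusted p 0.0548 to 0.206, against 1.44e-06 without mutant 1; log2 fold change -3.54 to -3.10 over all 6) and unfiltered log2(TPM + 1) (-2.18, adjusted p = 0.241). The 16 changed lists fell to 0 with an estimated correlation and 2 by fry. In mutant 1 alone the oligodendrocyte list went from lower without passing to higher (median 0.30, adjusted p = 0.000112, and 0.663 with an estimated correlation). A-type (0.000239) and other potassium channels (0.0292), lysosome and autophagy (0.00994), antigen presentation (0.00112) and clock genes (0.0241) newly passed there too, each lost with an estimated correlation (adjusted p = 0.577 to 0.805). The immediate early list turned down without passing (-0.15, adjusted p = 0.224). Ensheathing glia (0.381), homeostatic microglia and choroid plexus (0.157 each), oligodendrocyte precursors and mitochondrially encoded genes (0.228 each) and ependymal cells (0.619) no longer passed. The share of called genes near Mitf passed under no alternative, with 0 to 45.3% over the fits without a library. The other deposited table left every count, list and Mitf transcript as it was. Named genes gave 848 tests on the same side of the threshold, 146 no longer past it, 90 newly past it and 0 reversed among calls. In 36 of the 848 the sign changed with neither value called, and likewise in 25 of 493 list tests; a further 46 list tests no longer passed, 29 newly did and 2, the oligodendrocyte and immediate early lists above, turned direction. At this spread, the simulation recovered 4.62% of 2-fold, 50.8% of 4-fold and 72.1% of 8-fold changes, so an uncalled gene may have changed by that much or more. Genes that varied widely among the mutants, such as Cdhr1, did not pass at larger differences.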

Other observations

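In mutant 1 alone against wild type, a fit added after the data were examined, some interferon and antigen presentation genes were higher. Of 21 tested members of the type I interferon list, Ifi27, Ifit2, Ifitm3 and Rtp4 passed and 11 were higher adjusted over the list alone (median log2 fold change 0.77, camera adjusted p = 9.14e-12). The adjusted p was 0.663 with an estimated correlation. H2-Q4, H2-Q6 and Tapbp, which act in antigen presentation by class I molecules, passed among 18 members (camera adjusted p = 0.00112, and 0.726 with an estimated correlation). The cholesterol synthesis list had 5 of 22 members higher, among them Fdft1, Insig1 and Hmgcs1, and 11 adjusted over the list alone (camera adjusted p = 2.10e-07, and 0.317 with an estimated correlation).

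Of the clock genes, Dbp, Ciart, Bhlhe41 and Cry2 were higher and Cry1 lower in mutant 1 alone, out of 17, and adjusted over the list alone 8 were higher and 6 lower (camera adjusted p = 0.0241, and 0.577 with an estimated correlation). Among lysosomal genes Ppt1, Gaa and Atg9b were higher and Gla lower, out of 41 (camera adjusted p = 0.00994, and 0.663 with an estimated correlation). The lone mutant library is assumed to vary like the wild types. In the simulation of this fit 35 of its 151 calls were false (23.2%), so any single call from it is uncertain. Tissue markers moved in the same library, with the median tectum marker 2.08 above wild type and the oligodendrocyte list higher (camera adjusted p = 0.000112, and 0.663 with an estimated correlation).

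The tests of the patterns that follow were chosen after the results they bear on were seen, except the tectum test and the count over splits. The first pattern is that markers of bulb neurons were high in mutants 2 and 3 and low in the other 4 libraries. Over 30 markers the median rise over the wild-type mean was 0.09 in mutant 1, 3.11 in mutant 2 and 2.95 in mutant 3 on the log2 scale. A difference in library size left uncorrected is argued against, since 2.954 exceeds the log2 ratio of the largest to the smallest library, 0.757. The levels were already scaled for library size, so other effects of depth are not tested by this. Another brain region in the other 4 libraries is a candidate explanation: 16 of 16 cerebellum markers, listed once Itpr1 but not the others had been seen, of which Itpr1 was the most abundant (4281 to 5325 CPM there, 258 and 177 CPM in mutants 2 and 3) and Fat2 was further apart (765 to 804 CPM, 0.552 and 0.732 CPM), lay higher in each of the 4, by at least 1.34 on the log2 scale; 12 of the 16 also reached 1 CPM in mutants 2 and 3 and 1 stood on a fixed list. Loss of Mitf cannot be the source of the levels in the wild types, which held 15.2 to 17.3 CPM of Mitf. This follows from their genotype and was not a test. That all 16 cerebellum markers lay higher there than in mutants 2 and 3 restates the pattern. Cdhr1 reached at most 0.652 CPM in the wild types. For the rise in mutants 2 and 3 loss of Mitf stays open. The count of 2 of the 3 mutant libraries with a rise of the required size follows from the pattern itself, and mutant 1 without it is a single library.

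The second pattern is a set of genes higher in mutant 1 than in every other library. Among tested genes with a mean log2 CPM of at least 0, 8 were so by over 4-fold. The greatest excess was in the homeobox genes Shox2 (18.9 CPM against at most 0.329), Six3 (13.9 CPM) and Lhx9 (21.1 CPM). Six3os1 (4.89 CPM) and Tcf7l2 (95.7 CPM) came next. A candidate explanation is adjoining midbrain roof tissue in mutant 1: of 8 tectum markers listed before their values were seen, 6 lay higher there than in every other library by over 1 on the log2 scale, namely Tfap2d, Pou4f3, Gata3, Tal1, Sox14 and Pou4f1, all below 10 CPM. Of these 8 markers, 0 stood on another list. No biological explanation was tested.

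The third pattern is 119 genes shifted alike in all 3 mutant libraries, 57 up and 62 down, apart from Mitf, each with a gap of over 1 between the groups and a range below 1 among the mutants on the log2 scale. A call was not required, and edgeR adjusted p ran from 0.000376 to 0.169. Gm13302 and Gm3893 had 0 counts in all 3 mutants, and Gm14117 lay at their level of -5.77 on the log2 scale in each. At that floor the range is below 1 by itself. How many such genes chance would give was not computed. For the genes shifted down, dilution by admixed tissue in mutant 1 is argued against: their median fall in that library was -1.84, while the cerebellum markers, which dilution would lower alike, moved by -0.103. The required gap fixed a fall of over 1 in advance, so only the cerebellum value was free to differ. Less of another tissue in mutant 1 stays open and untested, as the median choroid plexus gene moved by -0.91 there. Linked variants carried by the mutant stock stay open: 19 of the 119 lay within 1 Mb of another and a share of 0.47 of 10000 random gene sets had as many, but the set leaves out the called genes Gm13301 and Gm5859 of the chromosome 4 family. On chromosome 4 there were 16 members, 7 of them within 1 Mb of another, including Hdhd3 and Bspry beside Alad, a gene outside the set at 22.5 to 23.4 CPM in wild type and 72.1, 45.3 and 38.5 CPM in mutants 1 to 3. Loss of Mitf, unlinked variants and, for the genes shifted up, admixed tissue stay open and untested.

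Of the 10 splits of the 6 libraries into 3 and 3, 1, the genotype split, gave 35 called genes and the highest of the others gave 0. With 10 splits no share below 0.05 can be reached. Between genotypes the other lists added later did not pass camera, with adjusted p = 0.978 for tectum, hippocampus and hypothalamus, 0.435 for thalamus, and 0.409 for eye and for midbrain and hindbrain.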
